A study of Homo sapiens with 2 samples.

How the data were processed

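Gene expression was measured on Affymetrix expression arrays in OECM1 cells, an established human head and neck cancer cell line. There were 2 arrays, 1 of cells transfected with a plasmid carrying the microRNA let-7i and 1 of cells transfected with the empty mCherry plasmid. Each array carried biotin-labelled cRNA made from total RNA, per the labels' protocols. The value table gave 1 intensity, called signal below, for each of 54675 probe sets on each array. The authors' values were MAS5 signals, per the submitters' processing notes. The software version, the detection calls and the scanner files were not given in the sources used here. The deposited intensities were on a linear scale, from 0.105 to 46841, and the mean after trimming 2% at each end was 500.1 on both arrays. They had therefore already been scaled to 1 target, and no further scaling was applied. MAS5 scales whole arrays by 1 factor, so a general shift in RNA content between the cultures would not be visible in these values.

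Probe sets were named from GEO's platform annotation and checked by gene identifier against a table of current human gene symbols. Of the probe sets other than the 62 Affymetrix controls, 41091 named 1 gene, 1801 named several genes and 11721 named none in the annotation used here. Only probe sets that named 1 gene were used for genes. Probe sets were kept when the mean of both signals was at or above its median over all probe sets (59.2), which left 27307 probe sets and 12164 genes. Where several kept probe sets named a gene, the one with the highest mean signal gave its value. Differences were taken as log2(signal + 4.62) of the let-7i array minus the same of the empty-vector array, with the 10th percentile of all signals as pseudocount, which understates the change of dim genes. Folds quoted with a gene are ratios of the deposited signals of that probe set, unless another is named. Other probe sets of a gene can fall short of the 2-fold rule, and the text gives them for some genes only.

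With no detection calls at hand, background was read from the 27 probe sets for bacterial genes (Dap, Lys, Phe, Thr, Trpn) that lay at low signal on both arrays. The brightest of these had a signal of 39.8 on the let-7i array and 42.7 on the empty-vector array. A gene at or below that value on 1 array has only a bound there. The fold of that probe set was computed against the ceiling and is written "at least", and other probe sets of the gene can give smaller folds. The order of genes given as bounds is not known.

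The groups held 1 array each, so no test between conditions was possible, no p-value is given, and the number of arrays limits the precision. A gene was counted as different by a rule of size, a difference of at least 1 on the log2 scale (2-fold). As a technical measure, the SD of the difference among probe sets of the same gene was 0.41, which covers neither culture nor array variation. The rules for counting, 21 gene lists and the rule for naming genes were fixed at the same stage as the alternatives given below. For each list, the median difference of its kept genes was placed among 10000 random lists of the same size, matched on mean signal in 10 bins. A list is said to stand apart where its median lay at or below the 2.5th or at or above the 97.5th percentile, as a description of these 2 arrays. The let-7 targets came from general knowledge of the microRNA. NEDD9 and DOCK3 were recalled from literature on let-7i in head and neck cancer cells, which may include the study of these samples.

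The text names 4 sets of genes. The first holds the 12 highest and 12 lowest differences supported by at least 2 kept probe sets that all differed by 1.5-fold or more in the same direction. The second holds the 5 highest and 5 lowest among genes with 1 kept probe set. The third takes up to 4 members at each end of every list, of which the text gives some. The last is a fixed set of let-7 and migration genes. Members outside these sets were chosen after their values were seen and are used only to fill out a list's description. Of the fixed set, 3 genes had no probe set naming them alone; these genes and 1 of the 21 lists are not reported here.

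Alternatives fixed before the data were examined were 3 scalings, 2 pseudocounts, 2 filters and 2 rules for probe sets. Values at background set to the ceiling, a pseudocount of 100 and the omission of chromosome 9 genes were added after seeing the data. A search for let-7 seed sites in 3' untranslated regions was not run, because no transcript sequences were used here. Simulated arrays with 12177 genes were built from the real signals with the spread between probe sets. In them, 100% of 50 genes changed by 2 on the log2 scale passed the 2-fold rule. So did 54% of 50 genes changed by 1 and 1.09% of unchanged genes. The simulation held no variation between cultures or arrays, so the last share is not a rate of false calls for the real arrays. Of 200 lists of 30 random genes, 4.5% stood apart with no shift and 92.5% with a shift of 0.3. The first share follows from the rule itself. Random lists treat genes as independent, which genes of a list need not be, so the percentiles below give no probability. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.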

Results

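The study asked which genes differ in OECM1 cells transfected to overexpress let-7i, a microRNA of the let-7 family. Total RNA of cells transfected with the let-7i plasmid was profiled on 1 array, and RNA of cells transfected with the empty mCherry plasmid on another. There were no replicates, so every difference below describes these 2 cultures. Both arrays had like signal distributions, with medians of 59.1 for let-7i and 60.8 for the empty vector. The log2 signals of the kept probe sets correlated at r = 0.947 across probe sets, which are not independent replicates. RNA integrity as the control probe sets show it was close on both arrays. The 3' to 5' signal ratio of GAPDH was 0.981 with let-7i and 1.01 with the empty vector, and that of beta-actin was 1.18 and 1.21. The hybridisation spike bioB had signals of 879 and 865. The control probe set for the middle of 28S ribosomal RNA was dimmer with let-7i, at 3359 against 5728.

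Of 12164 genes, 531 (4.37%) were at least 2-fold higher and 579 (4.76%) at least 2-fold lower in the let-7i array. Among the higher genes that several probe sets could judge were TNFAIP6, an inflammation-induced hyaluronan-binding protein (7636 against 109, 69.9-fold), the chemokine CCL5 (3341 against 145), the mesenchymal transcription factor ZEB1 (1424 against 63.3, 22.5-fold), and the cytokine IL1B (13025 against 818, 15.9-fold). The 5 kept probe sets of the collagen gene COL6A1 gave from 2.43-fold to 19.6-fold, and the 3 kept ones of COL13A1 from 1.64-fold to 18.7-fold. By their brightest probe sets, at background with the empty vector, the interferon-induced GTPase GBP5 was at least 14.5-fold, DTNBP1 at least 6.90-fold, the glycoprotein CHI3L1 at least 6.87-fold and GSAP at least 4.02-fold higher. Probe sets of the growth factor BMP2 gave at least 4.87-fold and 2.33-fold (143 against 61.1), and those of ARFGEF3 at least 5.96-fold and 2.61-fold. The lower genes included several pregnancy-specific glycoproteins, which are normally made by the placenta: PSG6 was 17.1-fold, PSG9 17.0-fold and PSG5 13.1-fold lower by their brightest probe sets. The 3 probe sets of PSG1 gave at least 21.5-fold, 13.5-fold and 7.16-fold. These paralogs share sequence, and their probe sets may share signal, so the individual values are uncertain. The G protein regulator RGS7 was 17.6-fold lower by its brightest probe set (274 against 4819) and 2.74-fold by the other. By their brightest probe sets CD22 was 13.0-fold, FGD3 9.41-fold, the calcium channel subunit CACNG4 7.78-fold and C1orf116 7.63-fold lower. The smallest folds of their other probe sets were 3.99 for FGD3, 3.11 for CACNG4 and 4.07 for C1orf116. The estrogen sulfotransferase SULT1E1 was at least 4.64-fold lower. The formin DIAPH2 was lower by at least 6.16-fold and by 3.99-fold in its probe sets, and LINC02481 by at least 4.97-fold and by 3.08-fold.

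Among genes with 1 kept probe set, the chemokine CXCL1 had a signal of 14016 with let-7i and was at background (19.2) with the empty vector, a fold of at least 328. The S100 family genes S100A8 (4155 against 49.7, close to background), S100A9 (at least 77.4-fold) and S100A7 (at least 27.1-fold) and the granulocyte growth factor CSF3 (at least 22.1-fold) were higher as well. At the other end, the GABA receptor subunit GABRP was at background with let-7i and at 1912 with the empty vector, at least 48.0-fold lower. The immediate early transcription factor FOS was 25.7-fold lower (374 against 9627). LINC00648 was at least 9.07-fold, the transporter SLC16A9 at least 7.94-fold and the placental phosphatase ALPP at least 7.15-fold lower. Of the 2-fold calls, 108 higher and 85 lower genes rested on a value at background. Of those judged by several probe sets, 217 of 234 higher and 191 of 222 lower genes had all their probe sets on the same side. The counts depended on how dim probe sets were treated, from 245 higher and 230 lower with the filter at the 75th percentile to 1685 and 2018 with no filter.

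**Figure D1:**
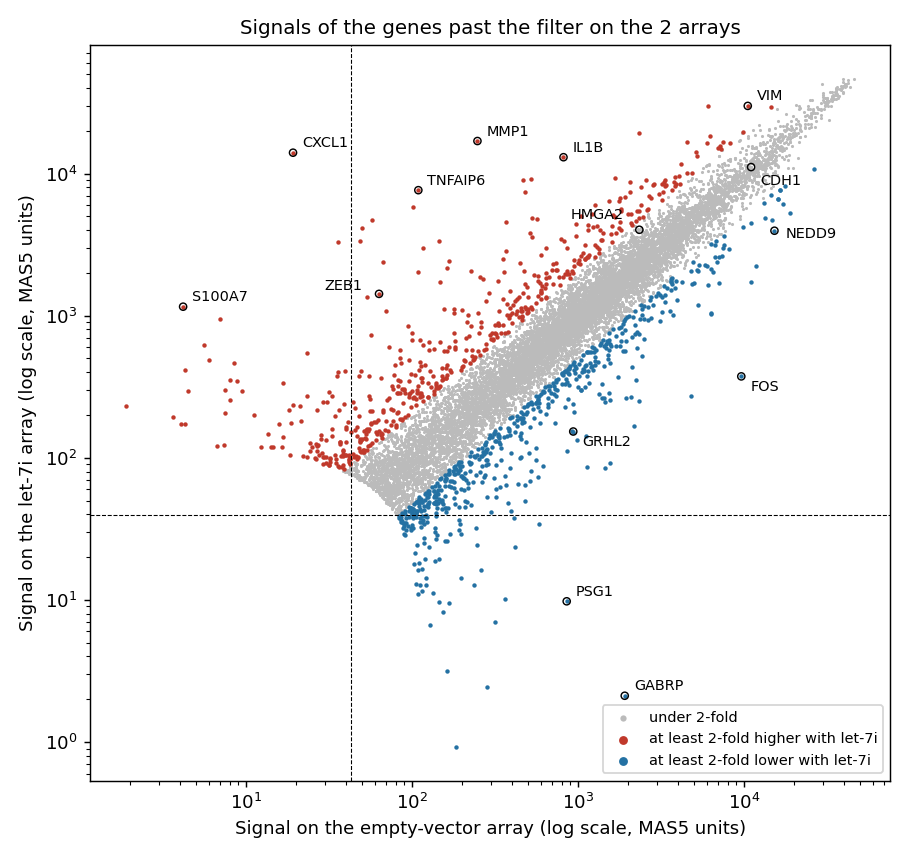
Signal on the let-7i array (vertical, log scale, MAS5 units) against the empty-vector array (horizontal, log scale, MAS5 units) for the 12164 genes past the filter, 1 point per gene, with dashed lines at the background ceilings of 39.8 and 42.7. Red points mark the 531 genes at least 2-fold higher and blue points the 579 at least 2-fold lower with let-7i; CXCL1 and S100A7 lie left of the background line, and GABRP and PSG1 below it.

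The first list asked whether known let-7 targets were lower with the let-7i plasmid, although the level of let-7i itself was not checked. They were not lower as a group. Of 54 measured targets, 20 had a negative and 34 a positive difference, and 2 were at least 2-fold lower while 4 were at least 2-fold higher. The lower genes were STARD13 (2.76-fold), and THBS1, the matrix protein thrombospondin 1 (2.72-fold). RDH10, a retinol dehydrogenase, was 1.93-fold lower. TAF9B was 1.88-fold lower by its brightest probe set, but its 5 probe sets disagreed in direction. The higher genes were the protease PAPPA (177 against 59.1), the cell cycle phosphatase CDC25A (2.49-fold, from dim probe sets that disagreed in direction), the phosphate transporter SLC20A1 (2.35-fold) and the kinase MAP4K4 (2.34-fold). These calls rest on the brightest probe sets. Other kept probe sets fell short of the rule, with differences down to 0.36 for PAPPA, 0.64 for SLC20A1 and 0.91 for MAP4K4. The same held for the lower gene THBS1, with -0.70. HMGA2, a chromatin protein and classic let-7 target, was 1.72-fold higher (4022 against 2341), and its 4 probe sets gave differences from 0.14 to 1.76. IGF2BP2, an RNA-binding protein, was 1.61-fold higher. LIN28B (156 against 170), IGF2BP1 (433 against 479), IGF2BP3 (3736 against 4092), CDK6 (2689 against 2676) and MYC (21779 against 21583) differed by 1.11-fold or less by their brightest probe sets, although other probe sets of CDK6, IGF2BP1 and IGF2BP3 differed by more. All 3 kept probe sets of IGF2BP3 were lower, one by 1.40-fold (1798 against 2520). The cyclin CCND1 was 1.54-fold lower, and DICER1, the nuclease that makes mature microRNAs, 1.36-fold lower (2974 against 4056). The median difference of the list was 0.018, at the 78.3th percentile of matched random lists, and it did not stand apart under any of the alternatives. MicroRNA machinery genes had a median of 0.028 and a mean of -0.018 over 22 genes (71.0th percentile), with none at 2-fold. DDX5 was 1.63-fold, TNRC6B 1.58-fold and TARBP2 1.38-fold lower, and TUT7 had 1178 against 1763. AGO3 was 1.48-fold, HNRNPA1 1.35-fold and PRKRA 1.33-fold higher. ZCCHC7, 1.42-fold higher, was in the list and its median, although it is not an established gene of microRNA processing. Other probe sets of TARBP2, TUT7 and AGO3 disagreed in direction.

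The second list held NEDD9 and DOCK3, recalled from the literature as let-7i targets in head and neck cancer cells, with genes of the Rac migration pathway. That literature may describe the study these arrays come from, so the choice of both genes is not independent evidence of their direction. NEDD9, a scaffold protein of focal adhesions, was 3.85-fold lower in the let-7i array (3960 against 15246), and all its 4 kept probe sets were lower, by 0.38 to 1.97 on the log2 scale. DOCK3, an activator of Rac, was at background on both arrays and gives no comparison. RAC1 itself differed by 1.05-fold (14047 against 14777), with probe sets on both sides. VAV3, another Rac activator, was 2.18-fold lower, and DOCK4 was 3.18-fold higher. WASF3 was 1.53-fold and the NEDD9 relative BCAR1 1.63-fold higher. Over 23 measured genes the median was 0.080 (86.9th percentile).

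Genes for cytokines, chemokines and NF-kB targets showed the widest separation of the lists fixed before the data were examined. Of 29 measured members, 18 were at least 2-fold higher in the let-7i array and 1, TNFAIP2 (2.66-fold), was lower. Besides CXCL1 and CSF3, the cytokine IL24 was 82.1-fold higher (4720 against 57.5) and the chemokine CXCL3 57.6-fold higher (5828 against 101). CXCL8 (29885 against 6077, 4.92-fold), CXCL2 (8.29-fold), IL6 (4890 against 530, 9.23-fold), IL1A (15.5-fold), PTX3 (17.8-fold) and the prostaglandin synthase PTGS2 (5.50-fold) were also higher. The feedback inhibitor NFKBIA was nearly level (6902 against 6501), IL1RN, the antagonist of IL-1, had 109 against 195, and TNFSF10 had 622 against 979. The list median was 2.30 (100th percentile), and it stood apart in the same direction under all 12 alternatives, with 1.51 without the filter and 1.49 with the pseudocount of 100. Blood cell markers did not accompany it as a group. By their brightest probe sets, PTPRC had a signal of 8.05 with let-7i and 50.3 with the empty vector, LYZ 52.0 and 2.31, and TYROBP 5.87 and 22.1, all at or near background; CD14, at least 7.86-fold higher (335 against 16.7), was the 1 measured member past the 2-fold rule. The blood list had a median of 0.15 over 5 measured genes (76.6th percentile), among them ITGAM (60.6 against 65.1), CD79A (144 against 138), CSF1R (110 against 98.7) and HBB (287 against 214). Another HBB probe set was at least 3.39-fold lower.

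Interferon-stimulated genes differed far less. Of 36, 3 were at least 2-fold higher, OAS2 (3.36-fold), XAF1 (2.26-fold) and OASL (2.11-fold), and 1, SAMD9 (2.22-fold), was lower. ISG20 was 1.85-fold higher by its brightest probe set and at least 5.43-fold by the other, CXCL10 1.83-fold lower, and 16 members had a negative difference, among them ISG15 (9613 against 9811). The median of 0.18 stood apart at the 99.2th percentile. It turned to -0.080 (27.7th percentile) when dim probe sets were left out at the 75th percentile.

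Mesenchymal genes were higher and epithelial junction genes lower in the let-7i array. Of 25 mesenchymal genes, 12 were at least 2-fold higher and none at least 2-fold lower. They included the gelatinase MMP2 (2975 against 116, 25.6-fold), ZEB1, the collagen cross-linker LOX (12.4-fold), the matrix protein TNC (7.44-fold), ZEB2 (5.80-fold), FAP (4.97-fold) and the intermediate filament vimentin (VIM, 29911 against 10530, 2.84-fold). The other kept probe set of TNC gave a difference of 0.92 on the log2 scale, under the 2-fold rule. TWIST1 was 1.20-fold lower (789 against 947), COL1A2 1.95-fold, CCN2 1.57-fold, AXL 1.35-fold and ITGB3 1.26-fold lower. The median was 0.89 (100th percentile). No kept member had a value at background, so setting such values to the ceiling could not test this list. Of 29 epithelial junction genes, 10 were at least 2-fold lower and none at least 2-fold higher. The transcription factor GRHL2 was 6.12-fold lower (153 against 936), the small GTPase RAB25 3.37-fold, the tight junction genes CLDN4 3.30-fold and MARVELD3 3.16-fold, the splicing regulator ESRP1 2.46-fold and plakoglobin (JUP) 2.14-fold lower. CDH1, which encodes E-cadherin, did not go with them, at 11103 against 11028. ST14 was 1.89-fold, TJP3 1.52-fold, DSC2 1.46-fold and GRHL1 1.28-fold higher, GRHL1 with probe sets on both sides. The median was -0.72 (0th percentile). Both lists stood apart under all 12 alternatives. Among markers of fibroblasts, endothelium and other lines, DCN was at 130 against 108, LUM at 37.6 against 112 and PECAM1 at 343 against 298. Of the others measured, AFP had 77.3 against 61.4, TTR 65.0 against 69.1, CDH5 158 against 220 and SNAP25 143 against 175. Their median was -0.081 over 7 genes (48.6th percentile).

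Genes for matrix proteases had 7 members at least 2-fold higher and 1 lower of 27. Interstitial collagenase MMP1 was 68.3-fold higher (16932 against 248), and MMP10 was at least 11.4-fold and MMP3 at least 9.72-fold higher. Their inhibitor TIMP3 was 4.22-fold lower, while TIMP2 was 1.43-fold, SERPINB5 1.59-fold and MMP11 1.40-fold lower. The median was 0.32 (99.97th percentile), and the measured member MMP2 also belongs to the mesenchymal list. The squamous list split. KRT15 (2.99-fold), KRT80 (3.56-fold) and S100A2 (2.14-fold) were lower, as was KRT7 by its brighter probe set (5.30-fold), although its other kept probe set differed by 0.13 on the log2 scale the other way. The elafin gene PI3 was 6.21-fold higher along with S100A7, S100A8 and S100A9. Over 18 genes the median was -0.40 (0.08th percentile) but the mean was 0.67, and the median no longer stood apart with no filter (-0.14, 18.3th percentile).

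**Figure D2:**
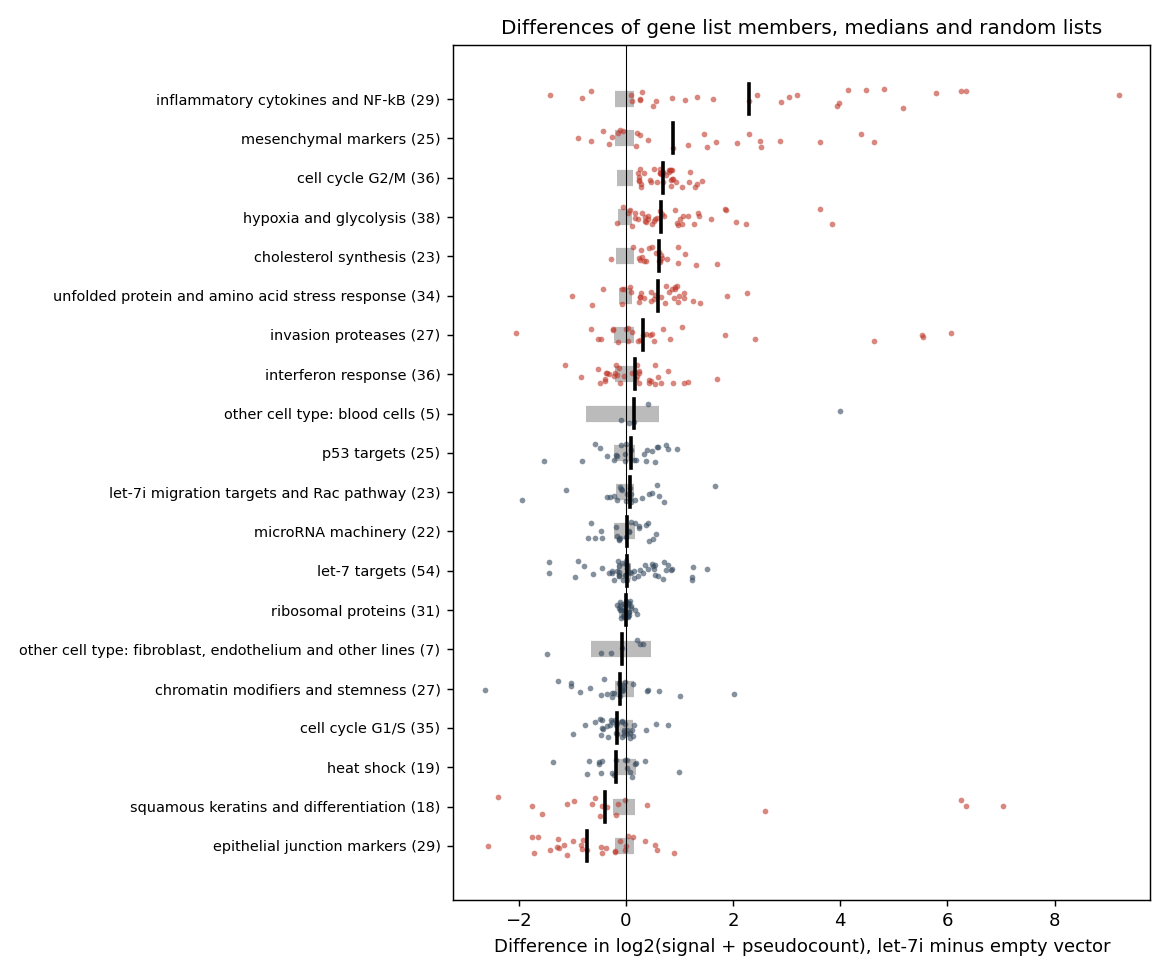
Difference in log2(signal + pseudocount), let-7i minus empty vector, for each kept member (points) of 20 lists, with the number of members in parentheses, the list median (black bar) and the central range of medians of 10000 matched random lists (grey band). Lists whose median lay outside the band have red points; cytokine genes have a median of 2.30, epithelial junction genes one of -0.72, and let-7 targets one of 0.018.

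Mitotic genes were higher in the let-7i array, and replication genes were not. All 36 G2/M genes had a positive difference, 6 of them at least 2-fold, with HMMR at 2.67-fold, the anaphase activator CDC20 at 2.51-fold, securin (PTTG1) at 2.44-fold and CENPF at 2.29-fold higher. The other kept probe sets of HMMR and CENPF gave differences of 0.72 and 0.69, under the 2-fold rule. The smallest differences were those of CENPA, MAD2L1, CDK1 and KIF20A, from 1.18-fold to 1.19-fold. The median was 0.70 (100th percentile). Of 35 G1/S genes, 25 had a negative difference and none reached 2-fold. The uracil glycosylase UNG was 1.98-fold, the sliding clamp PCNA 1.70-fold, and GINS2 1.39-fold lower, and MCM2 had 1934 against 2902. CDC6 was 1.73-fold, ORC6 1.49-fold, CDC45 1.30-fold and EXO1 1.11-fold higher. The G1/S median was -0.16 (4.71th percentile).

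Metabolic and secretory stress genes were higher as groups. Of 38 hypoxia and glycolysis genes, 14 were at least 2-fold higher and none lower, among them the glucose transporter SLC2A3 (15.4-fold, with probe sets that can share signal with SLC2A14), LOX, and the prolyl hydroxylase P4HA2 (4.17-fold), and ANGPTL4 was at least 2.45-fold higher. GAPDH was 1.06-fold and CA12 1.03-fold higher, and PFKL 1.12-fold and ANKRD37 1.04-fold lower, PFKL with probe sets on both sides. The median was 0.66 (100th percentile). Of 34 genes of the unfolded protein and amino acid stress response, 6 were at least 2-fold higher, with the stress transcription factor DDIT3 at 4.79-fold, SDF2L1 at 3.69-fold, the disulfide isomerase PDIA4 at 2.59-fold and MANF at 2.39-fold. The serine synthesis gene PHGDH was 2.00-fold, ATF3 1.55-fold, PSAT1 1.35-fold and CHAC1 1.06-fold lower. The median was 0.59 (100th percentile). Cholesterol synthesis genes had 22 of 23 positive differences and a median of 0.61 (100th percentile), with the sterol carrier STARD4 (3.26-fold), INSIG1 (2.47-fold) and DHCR7 (2.15-fold) past the 2-fold rule and MVD at 1.97-fold. SREBF2 was 1.21-fold lower by its brightest probe set and 1.20-fold and 1.39-fold higher by the others. SQLE (1.09-fold), SCD (1.19-fold) and MVK (1.20-fold) were higher by their brightest probe sets, and other probe sets of SCD gave up to 1.94-fold. The protease, G2/M, hypoxia, stress response and cholesterol lists stood apart in the same direction under all 12 alternatives.

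The remaining lists did not stand apart. Heat shock genes had a median of -0.19 over 19 genes (3.35th percentile), with DNAJB1 2.58-fold, HSPB8 1.67-fold and DNAJB4 1.61-fold lower and the collagen chaperone SERPINH1 1.98-fold higher. A probe set shared by the heat shock genes HSPA1A and HSPA1B was 2.34-fold lower (2594 against 6058). Another, shared also with HSPA1L, was 2.64-fold lower (3891 against 10268). Both named several genes, so they did not enter the median, and both were chosen after their values were seen. Chromatin modifiers and stemness genes had a median of -0.11 over 27 genes (17.2th percentile). In that list the Notch target HES1 was 6.22-fold lower (1021 against 6353), and SOX9 (2.41-fold), ALDH1A3 (2.05-fold) and ABCG2 (2.04-fold) were also lower, while ALDH1A1 was at least 4.22-fold, the methyltransferase DNMT3B 2.02-fold, NOTCH1 1.54-fold and DNMT1 1.32-fold higher. Targets of p53 had a median of 0.10 over 25 genes (90.7th percentile), with GADD45B 2.91-fold and BAX 1.78-fold lower and CCNG1 1.93-fold and GADD45A 1.72-fold higher. Ribosomal protein genes, included as an abundant reference group, had a median of 0.00081 and a mean of -0.00098 over 31 genes (62.4th percentile), between RPS9 (1.13-fold lower) and RPS18 (1.15-fold higher).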

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

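The tests of explanations in this part were all chosen after the results were seen. Of the 4143 kept probe sets that named no gene or several genes, and so entered no list or count above, 211 were at least 2-fold higher and 238 at least 2-fold lower in the let-7i array. Among them, a probe set shared by SAA1 and SAA2, the acute phase serum amyloid genes, was 21.0-fold higher (3707 against 177). A probe set with no gene named in the annotation used here was 43.5-fold higher (1950 against 44.8, close to background). Both were singled out after their values were seen.

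The cytokine and NF-kB genes formed the widest difference among the fixed lists. Both cultures were transfected with a plasmid, so an interferon response shared by them would cancel in the difference and is not tested by it. A response stronger in the let-7i culture would raise interferon-stimulated genes too, and their median was 0.18 against 2.30 for the cytokines. Of the 36 measured, 3 were at least 2-fold higher and 1 lower. GBP5, outside the list, was at least 14.5-fold higher by its brightest probe set. Scaling is argued against by the cytokine medians under quantile (2.31) and loess (2.30) scaling. RNA of leukocytes stays open, since 1 of 15 blood cell markers, CD14, was at least 2-fold higher with let-7i. Against it, CD3E was at least 2.03-fold lower (27.6 against 80.9) and PTPRC had 8.05 against 50.3. A further 6 markers were at or near background and gave no direction. An effect of let-7i, a difference between the cultures in density or handling, and drift between separately grown populations stay open and were not tested, because each condition had 1 array.

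The known let-7 targets were not lower as a group, and HMGA2 was higher. If the labels of the 2 arrays had been exchanged, the targets would stand above random lists, and if the labels are right and let-7i lowers these transcripts they would stand below. The observed 78.3th percentile lies in neither range, so exchanged and correct labels cannot be told apart by this list. Dim members that hide a decrease are argued against by the 75th percentile filter, under which the list lay at the 69.4th percentile. No probe set used here names let-7i, so its level was not checked.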

How the results depend on the processing

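Of the 10 lists that stood apart, 8 did so in the same direction under all 12 alternatives, of which 3 were chosen after seeing the data. The exceptions were the interferon list, with -0.080 at the 75th percentile filter and 0.12 with the mean of probe sets, and the squamous list, with -0.14 with no filter and -0.23 without _x_at and _s_at probe sets. Other lists came to stand apart in the direction they already had. These were heat shock with quantile normalization (-0.23), and G1/S (-0.19) and chromatin modifiers (-0.24) at the 75th percentile filter. The cause was not tested for any of these lists. KRT7 turned from lower to higher (0.13) without _x_at and _s_at probe sets, because its other probe set then gave its value. The 2-fold counts were 1685 higher and 2018 lower with no filter, which adds dim genes, 245 and 230 at the 75th percentile, which removes them, and 321 and 258 with the added pseudocount of 100, which shrinks their differences. Scaling to 1 trimmed mean changed almost nothing, since the deposited values had that scale already, and says nothing of stability. The blood and fibroblast lists had too few genes for a value at the 75th percentile filter, and the search for let-7 seed sites was not run. Signal over background limits the dim genes, and no setting addresses the spread between cultures.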

Other observations

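The groups and tests in this part were all chosen after the values were seen. Immediate early genes, which respond within minutes to growth signals, were mostly lower in the let-7i array. Of 23 measured, 10 were at least 2-fold lower, among them FOSB (at least 10.4-fold), ID3 (7.31-fold), EGR1 (5.30-fold, 2232 against 11825) and DUSP1 (2.42-fold), while FOSL1 (2.01-fold) and DUSP6 (2.30-fold) were higher. Their median was -0.89, below all matched random lists. All 8 measured pregnancy-specific glycoprotein genes were at least 2-fold lower. Their probe sets can share signal, so these are not 8 independent values.

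Collagens did not move as a class. Of 24, 6 were at least 2-fold higher and 2 lower, and the higher ones included COL4A6 (3.60-fold), COL8A1 (3.49-fold) and COL5A2 (2.23-fold). Integrins also split. The fibronectin receptor subunit ITGA5 was 4.22-fold and ITGA1 3.93-fold higher, while ITGB4, the hemidesmosome subunit, was 3.48-fold lower. A probe set shared by ITGB6 and LINC02478 was 11.6-fold lower (896 against 10424). Outside the lists, the steroid-activating enzyme HSD11B1 was 68.4-fold higher (3341 against 48.9, close to background), IL33 35.9-fold, IL13RA2 25.6-fold and NNMT 14.3-fold higher. The prostaglandin E synthase PTGES was 6.10-fold lower, although PTGS2, which acts before it, was higher.

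Genes along most of chromosome 9 were lower in the let-7i array. The median difference of its 512 genes was -0.27, with 73.6% below 0, whereas the medians of the other 22 chromosomes lay between -0.13 and 0.10. When the differences were shuffled over all genes 10000 times, any chromosome reached a median that far from 0 in 1 shuffle, with 0.28, and chromosome 9 itself went no lower than -0.13. The shuffle treats genes as independent and is too narrow a reference, since 13 of the other 22 chromosomes also stood apart from random gene sets matched on signal, so it gives no probability. In windows of 40 genes in chromosome order, the first 3 windows (KANK1 to ANKRD18A) had medians of 0.11, -0.16 and -0.012, and 72.5% of the genes of the second of them were below 0. The remaining 10 windows (FAM201A to TUBBP5) had medians from -0.54 to -0.23.

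Removing the trend with the number of genes within 1 Mb left a median of -0.23 for the chromosome, which argues against a trend with gene density as the whole cause. Fewer copies of a segment of chromosome 9 in the let-7i culture stay open as a hypothesis. The low windows formed 1 unbroken run at 1 of 4 cuts, -0.2, and 2 runs at -0.15, -0.25 and -0.3. The cuts were chosen after the windows were seen. The extra runs came from windows with medians near a cut, of -0.16, -0.30 and -0.23. The order of the windows therefore does not decide the hypothesis, and DNA was not measured. The lists above do not rest on this chromosome: without its genes the cytokine median was 2.30 and that of the let-7 targets 0.017.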
